A study of Mus musculus with 12 samples.

How the data were processed

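RNA from 12 samples of mouse conventional dendritic cells (cDCs, the antigen-presenting cells that fall into the subsets cDC1 and cDC2) was measured on Affymetrix gene arrays, 1 array per sample. Per the labels' protocols, total RNA was column-extracted and biotinylated cDNA was made with the Affymetrix WT Pico kit. The submitters' processing notes name Affymetrix Expression Console and RMA, the robust multi-array average, with no versions given in the sources used here. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probeset, so differences in total RNA between samples are removed from the values. The deposited values are intensities on a linear scale, from 6.96 to 18174, and log2 was taken of them here. The design fixed before the data were examined had assumed that log2 values were deposited; the tests are those written there, run on the log2 of the intensities. The values carry no detection calls. As a measure of background chosen after the data were seen, 1011 olfactory receptor genes, which dendritic cells are not expected to express, had a median of 4.23 and a 95th percentile of 5.82 on the log2 scale over all arrays. Where the dimmer group mean of a fold lies below 5.82, the fold is given as "at least", computed against 5.82, while log2 changes are those of the signals as measured. Further, no scan dates or batches are given in the sources used here. The number of arrays limits the precision.

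The value table holds 28853 probesets. GEO's platform annotation lists 23410 of them, of which 21789 have 1 gene symbol and 1621 have several; 5443 have no entry and are unnamed here. Probesets with 1 symbol were tested, and for the 999 genes with more than 1 probeset the brightest over all arrays was kept, which left 19938 genes. Among the genes named, the probesets of Kcnma1 disagree, the dimmer ones of Dnah6 and Arhgap42 changed less than the one kept, and those of Fabp5, Idi1 and Wdfy4 moved the same way. Of the probesets with 1 symbol, 21698 matched a mouse RefSeq gene by Entrez ID, and 0 symbols needed an update. No probe coordinates are printed, since no genome build is named for the probes. No column lay outside the labelled samples (0), and no arrays held identical values (0 pairs). Array medians lay between 68.6 and 72.8 intensity units. Replicates correlated at 0.993 to 0.997 over genes, and the median SD between replicates was 0.0779 to 0.094 on the log2 scale.

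Samples were grouped by their titles into 6 groups of 2. For the wild-type cDC2 samples the source name, description and cell type say cDC1 while the title says cDC2; the title was followed, as the protocol describes a CD172+ cDC2 sort. Sirpa, the gene for CD172a, averaged 11.82 on the log2 scale in these samples and 5.91 in the samples titled cDC1. The labels do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

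Each comparison was a contrast in 1 limma model (limma 3.58.1 in R 4.3.3; lmFit with 1 mean per group over all 12 arrays, then eBayes with 5.41 prior and 6 residual degrees of freedom). Benjamini-Hochberg adjustment ran over the 19938 genes of each contrast, and a gene was called at an adjusted p under 0.05. The 10 contrasts were wild-type cDC1 against cDC2, the high against the low level of each factor, IRF8 against IRF4 at each level, the interaction (IRF8 level effect minus IRF4 level effect), and transduced against wild-type cells (each high level against cDC1, each low level against cDC2). Standard errors are limma's. Overlaps of calls were tested with Fisher's exact test (two-sided) beside the number expected for independent lists. The contrasts overlapped share no arrays in their group means. They do share each gene's pooled variance, so their calls are not independent. The genes tested include 7266 with a mean below background in all 6 groups. If few of these can be called, the expected numbers are too low and the odds ratios too high.

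Before the data were examined, 29 gene lists with 657 genes were fixed, of which 58 genes were not measured. They cover cDC markers and regulators, antigen presentation, maturation, innate signalling, cell cycle and lipid handling, and markers of other cell types that the sort could hold. Lists were tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 29 lists. Counts of called members of these lists are given over all genes and, after them, adjusted over the list alone. Another pair of lists came from the wild-type comparison of this study: genes called and at least 2-fold higher in cDC1 or in cDC2. The size of each difference came from the wild-type arrays alone. The calls, however, used a variance pooled over all arrays, so the transduced arrays had a part in choosing these lists. The rule for named genes was also fixed beforehand: Irf4 and Irf8; the 10 largest rises and 10 largest falls per contrast among called genes whose groups do not overlap (no such condition in the interaction), leaving out predicted genes, clone names, pseudogenes and small RNAs; and up to 4 called members of each list with the largest change. Xcr1 is also named in the comparison of IRF4 levels, where it was not called. The second Kcnma1 probeset was named after its values were seen.

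The model was tested on simulated data with 3 runs of 19938 genes. Only a small share of the genes was changed, and the noise was normal and independent between genes and arrays. Most real contrasts call far more genes, and real replicate differences correlate, so the rates below need not carry over to the data. A log2 change of 1 was found in 98% of changed genes for the wild-type comparison, 97.5% for the IRF8 level, 98.5% for the IRF4 level and 84.6% for the interaction; a change of 0.5 was found in 43.8%, 46.8%, 40.3% and 9.45%. False calls made up 4.55%, 5.06%, 6.65% and 4.46% of calls. Alternatives were a filter on dim genes, all probesets or the mean of a gene's probesets, median centring, a second quantile normalization, cyclic loess, an intensity trend with robust eBayes, array weights, only the groups compared, a replicate block, stricter thresholds, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.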

Results

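The study compared cDCs made from bone marrow progenitors that lack the transcription factors IRF4 and IRF8 and were given 1 of them back. CD117-high progenitors of Irf4−/− Irf8−/− mice (C57BL/6) received retroviral Irf4 or Irf8 at a low or a high level and were cultured for 7 days with Flt3L, the growth factor that drives cDC development. MHC class II+ CD11c+ B220− cells were then sorted. Wild-type cultures were sorted further into cDC1 (CD24+ CD172−) and cDC2 (CD172+). The groups are called IRF4-low, IRF4-high, IRF8-low, IRF8-high, wild-type cDC1 and wild-type cDC2, with 2 arrays in each (12 in all). The stated purpose was to find expression signatures controlled in common or specifically by the 2 factors. Knockout cells without a returned factor were not analysed here, so the comparisons set levels and factors against each other. The titles name the levels only as low and high, so a level need not be the same amount for both factors. Differences between the factors, and the interaction, therefore cannot be told apart from differences in amount. The transduced cells were not sorted further by CD24 or CD172, so their values are averages over all cells in the gate. Changed shares of cell subsets and changes within cells cannot be told apart in any comparison of them. Changes are given as log2 change ± SE from limma with n = 2 per group, and levels as log2 intensity. A fold written "at least" has a dimmer group within the range of olfactory receptor genes, taken as background, and was computed against the top of that range (5.82). The median SE was 0.116 for a difference of 2 groups and 0.164 for the interaction.

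The signals of Irf4 and Irf8 separated the arrays by the factor returned. Irf4 read 11.28 and 10.93 in the IRF4-low arrays and 11.58 in both IRF4-high arrays, against 4.57 to 5.04 in the 4 IRF8 arrays. Wild-type cDC1 gave 6.17 and 6.26, and wild-type cDC2 9.20 and 9.24. Irf8 read 12.45 and 12.46 in the IRF8-low arrays and 12.95 and 13.10 in the IRF8-high arrays, beside 12.86 and 12.99 in wild-type cDC1 and 10.39 and 10.44 in wild-type cDC2. In the IRF4 arrays, made from cells without a functional Irf8 gene, the Irf8 probeset still read 10.10 to 10.96. Which part of each gene was deleted and where the probes lie are not given in the sources used here, so this signal does not check the labels. The step from low to high was small in signal: Irf4 rose by 0.48 ± 0.12 in the IRF4 arrays (1.39-fold, adjusted p = 0.0193) and Irf8 by 0.57 ± 0.12 in the IRF8 arrays (1.49-fold, adjusted p = 0.012). The Irf8 probeset rose as much in the IRF4 arrays (0.60 ± 0.12), where no Irf8 was returned. Its rise in the IRF8 arrays therefore cannot be credited to the returned Irf8. The Irf4 call was lost with only the groups compared (adjusted p = 0.11), with a second quantile normalization (0.052) and without IRF4-low replicate 2 (0.191), IRF4-high replicate 1 (0.0744) or IRF4-high replicate 2 (0.0647). The Irf8 call was lost without IRF8-low replicate 2 (0.0672) or IRF8-high replicate 2 (0.0917).

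**Figure D1:**
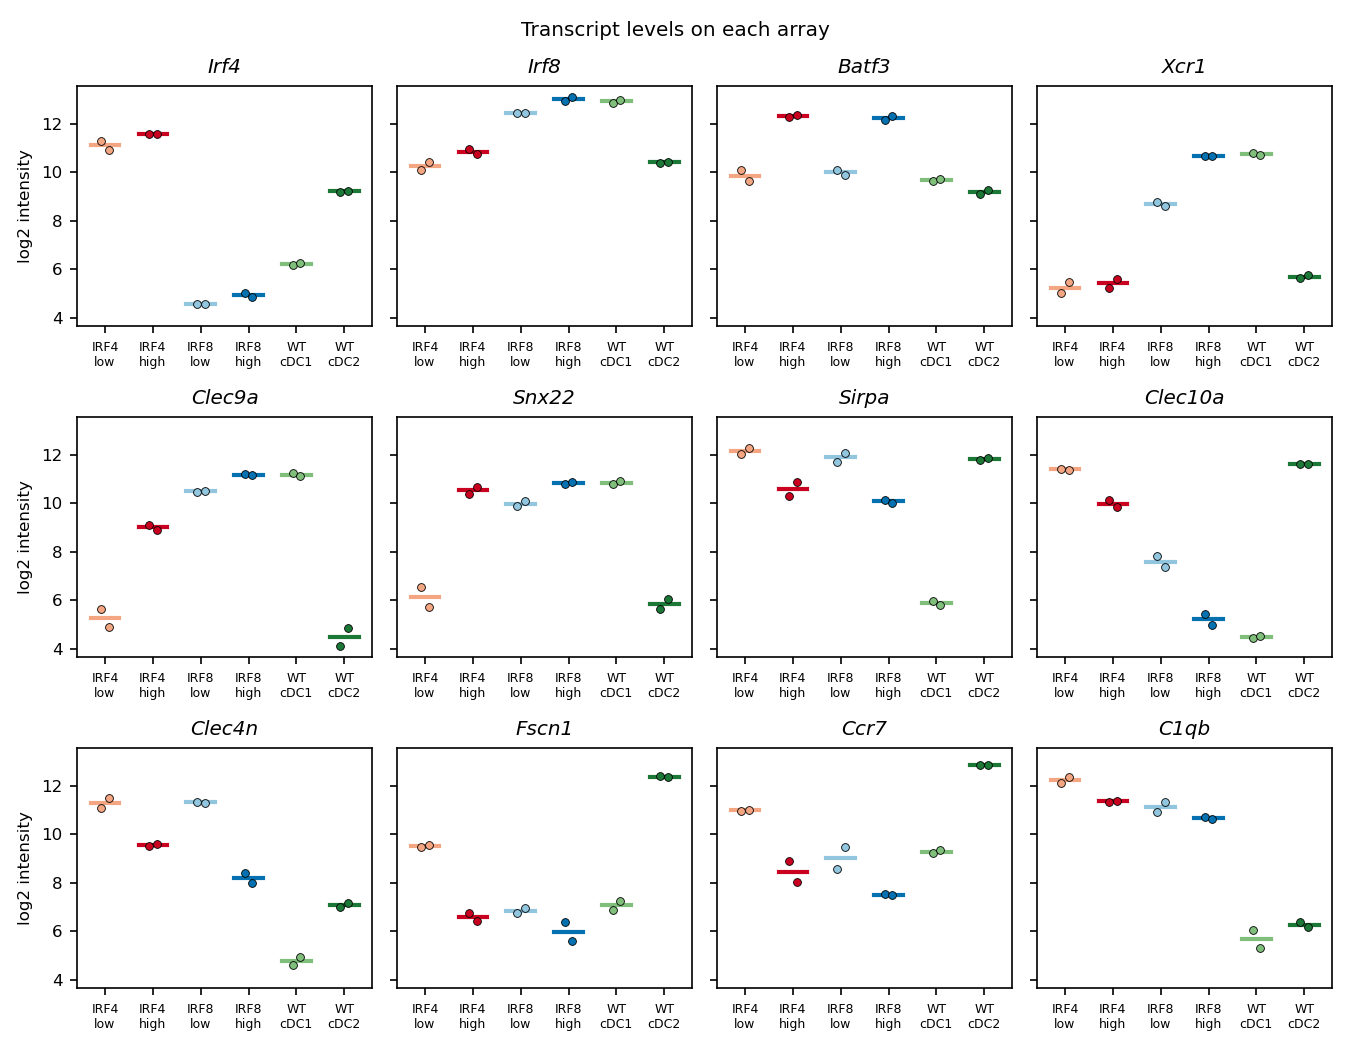
Log2 intensity (vertical axis) of 12 genes in the 6 groups, with 1 dot per array and a bar at each group mean. Irf4 and Irf8 follow the factor returned, Xcr1 lies between 8.60 and 10.80 in the IRF8 arrays and wild-type cDC1 and below 6 elsewhere, and Batf3 averages 12.32 and 12.24 at the high levels of IRF4 and IRF8 against 9.67 in wild-type cDC1.

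Wild-type cDC1 and cDC2 were compared to see which genes mark each subset in these cultures. Clec9a, a receptor for dead-cell debris used by cDC1, was at least 41.1-fold higher in cDC1 (6.71 ± 0.24, adjusted p = 4.75e-09). The chemokine receptor gene Xcr1 was at least 30.9-fold higher (5.06 ± 0.15, adjusted p = 1.11e-09), Snx22 31.9-fold and Tlr3, a sensor of double-stranded RNA, 55.3-fold. On the cDC2 side, the lectin gene Clec10a stood at −7.13 ± 0.17 (at least 55.8-fold lower in cDC1, limma adjusted p = 3.25e-10) and Cd33 at −6.10 (at least 57-fold). Sirpa stood at −5.92, but it encodes CD172a, on which these subsets were sorted, so the sort itself favours this difference. Irf8 was higher in cDC1 by 2.51 and Irf4 lower by 3.01 on the log2 scale (−3.01 ± 0.12).

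Of 27 measured cDC1 markers, 22 were higher and 3 lower in cDC1 (23 and 3 adjusted over the list alone), with Itgae, the integrin chain CD103, at 2.89 and Wdfy4 at 1.42 among the higher ones. Of 34 cDC2 markers, 24 were lower and 3 higher (25 and 3 adjusted over the list alone), Mgl2 (−5.07) and Cd209c (−4.43) among them. Maturation and migration genes stood higher in cDC2: 34 of 36 were lower in cDC1 and 1 higher (35 and 1 adjusted over the list alone), with Fscn1, an actin-bundling protein of mature dendritic cells, at −5.30 and the chemokine gene Ccl22 at −4.24. C-type lectin and Fc receptors (16 of 26 lower, 3 higher; 17 and 3 adjusted over the list alone), MHC class II presentation (11 of 23 lower, 1 higher; 13 and 5), cytokines and chemokines (11 of 29 lower, 1 higher; 12 and 3) and the ETS family and PU.1 partners (4 of 13 lower, 0 higher; 5 and 0) were lower in cDC1 as groups, and these 7 lists held in camera with either correlation. Among cell cycle genes 18 of 37 were higher in cDC1 and none lower (25 and 0 adjusted over the list alone; adjusted p = 0.282 with an estimated correlation), Cdk1 at 0.96 among them. The cDC1 transcription factors (5 of 6 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.0659 with an estimated correlation) included the inhibitor of DNA binding Id2 at 1.91, and the cDC2 transcription factors (4 of 9 lower, 2 higher, the same over the list alone; 0.125) included Zeb2 at −4.15. Plasmacytoid dendritic cell (pDC) markers (9 of 20 lower, 1 higher; 10 and 1 adjusted over the list alone), monocyte and macrophage markers (12 of 32 lower, 4 higher; 13 and 5), lysosome and lipid handling (14 of 23 lower, 2 higher; 15 and 4) and interferon-stimulated genes (15 of 40 lower, 6 higher; 15 and 8) passed only with the preset correlation, with adjusted p = 0.0608, 0.104, 0.209 and 0.817 with an estimated correlation.

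In all, 3146 genes were called between the wild-type subsets, 1562 higher in cDC1 and 1584 higher in cDC2, of which 280 and 579 differed by at least 2-fold. The count was 2049 without cDC1 replicate 2 and 1947 without cDC2 replicate 1.

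IRF8-high was compared with IRF8-low to ask which genes move with the amount of IRF8. At the high level, genes of cDC1 were higher and a broad set of lectin, Toll-like receptor and macrophage genes lower. Plpp1, a lipid phosphatase gene, rose by 3.64 ± 0.16 (12.5-fold, adjusted p = 4.71e-07), the lectin gene Clec4b2 by 3.04 and the inhibitory receptor gene Ctla4 by 2.91. Batf3, a transcription factor gene needed for cDC1 development, rose 4.71-fold (2.23 ± 0.14, adjusted p = 2.64e-06), and Xcr1 rose 3.97-fold, from a mean of 8.69 to 10.68. Among the falls were those of the fungal receptor gene Clec7a (−3.20 ± 0.14, adjusted p = 4.71e-07), Clec4n (−3.11), Clec4e (−3.10) and the cytokine receptor gene Il21r (−2.89).

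Of the cDC1 markers, 13 of 27 rose and none fell (22 and 0 adjusted over the list alone), and of 6 cDC1 transcription factors 4 rose and none fell (the same adjusted over the list alone), Batf3 and Zfp366 (0.66) among them. Of the cDC2 markers, 26 of 34 fell and 1 rose (the same counts adjusted over the list alone), and 5 of 9 cDC2 transcription factors fell and none rose (5 and 2 adjusted over the list alone), Zeb2 at −1.90. C-type lectin and Fc receptors fell in 16 of 26 cases with 1 rise (18 and 2 adjusted over the list alone), Toll-like receptors in 9 of 15 with 1 rise (10 and 2), with Tlr7 at −2.37 and Tlr2 at −2.17. Monocyte and macrophage markers fell in 15 of 32 cases and rose in none (21 and 0 adjusted over the list alone), with Cd14, the lipopolysaccharide co-receptor, at −2.11 and the growth factor receptor gene Csf1r at −1.92. Lysosome and lipid handling (9 of 23 fell, 0 rose; 16 and 0 adjusted over the list alone), pDC markers (7 of 20 fell, 0 rose; 9 and 0), cytokines and chemokines (10 of 29 fell, 1 rose; 13 and 3) and MHC class II presentation (5 of 23 fell, 1 rose; 7 and 1) also shifted down, and these 11 lists passed with either correlation. Cell cycle genes rose in 17 of 37 cases and fell in none (27 and 0 adjusted over the list alone), Nusap1 by 0.92 among them (adjusted p = 0.111 with an estimated correlation). Maturation and migration (15 of 36 fell, 4 rose; 19 and 5 adjusted over the list alone), interferon-stimulated genes (9 of 40 fell, 0 rose; 19 and 1), AP-1 and BATF family (3 of 15 fell, 1 rose; 5 and 1), ETS family and PU.1 partners (4 of 13 fell, 0 rose; 4 and 0), immediate early and stress genes (4 of 21 fell, 0 rose; 4 and 0) and integrins and adhesion (5 of 21 fell, 3 rose; 10 and 4) passed only with the preset correlation, with adjusted p = 0.0723, 0.334, 0.377, 0.0631, 0.303 and 0.0856 with an estimated correlation.

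No shift was called for the dendritic cell core genes (4 of 14 rose, 4 fell), MHC class I and cross-presentation (2 of 22 rose, 2 fell), the IRF family (1 of 8 rose, 1 fell), sterol synthesis (0 of 17 called), or the markers of neutrophils and granulocyte precursors (4 of 28 fell), mast cells and basophils (2 of 19 fell), eosinophils (0 of 7 called), B cells (1 of 15 fell), T and NK cells (1 of 14 fell), progenitors (3 of 16 fell, 1 rose) and erythroid cells and megakaryocytes (1 of 10 fell). The counts adjusted over the list alone are the same except for MHC class I and cross-presentation (2 rose, 3 fell), the IRF family (2 rose, 3 fell), progenitors (3 fell, 2 rose) and erythroid cells and megakaryocytes (3 fell). In all, 1609 genes were called, 676 higher and 933 lower at the high level. The count was 812 without IRF8-low replicate 2, 875 without IRF8-high replicate 1, and 873 with only the groups compared.

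IRF4-high was compared with IRF4-low in the same way. Here too cDC1 genes rose. Snx22 rose 21-fold (4.39 ± 0.23, adjusted p = 7.5e-07), from a mean of 6.14 to 10.53, beside 10.84 in wild-type cDC1. Clec9a rose at least 9.18-fold (3.75 ± 0.24, adjusted p = 4.85e-06), Tlr3 11-fold, the kinase gene Dapk2 at least 10-fold, Gatm, an enzyme of creatine synthesis, 10.4-fold, and Itgae 6.09-fold. Batf3 rose by 2.46 ± 0.14. Xcr1 did not pass the test: its means were 5.25 and 5.42 (0.17 ± 0.15, adjusted p = 0.578). Among the falls were those of the chemokine gene Ppbp (−3.12), Fscn1 (−2.94 ± 0.22, adjusted p = 1.05e-05), Ly6d (−2.91), the B-cell and myeloid receptor gene Cd72 (−2.88) and Apol7c (−2.67). Ccr7, the receptor for migration to lymph nodes, fell by 2.53 on the log2 scale.

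Of the cDC1 markers, 17 of 27 rose and 3 fell (20 and 3 adjusted over the list alone), and 4 of 6 cDC1 transcription factors rose and none fell (4 and 1 adjusted over the list alone), Id2 by 1.46. Of the cDC2 markers, 22 of 34 fell and 4 rose (24 and 4 adjusted over the list alone). Maturation and migration genes fell in 26 of 36 cases and rose in 3 (30 and 3 adjusted over the list alone), with Relb, an NF-κB subunit, at −1.76. Lysosome and lipid handling genes fell in 18 of 23 cases and rose in none (22 and 0 adjusted over the list alone), with Nr1h3, a lipid-sensing nuclear receptor, at −1.75 and the protease gene Ctsd at −1.35. Monocyte and macrophage markers fell in 16 of 32 cases with 1 rise (20 and 1 adjusted over the list alone), Mrc1 at −1.80 and the Fc receptor gene Fcgr1 at −1.73 among them. pDC markers fell in 14 of 20 cases with 1 rise (15 and 1 adjusted over the list alone), including Spib, an ETS factor gene, at −2.29. Toll-like receptors (11 of 15 fell, 1 rose; 11 and 2 adjusted over the list alone), C-type lectin and Fc receptors (14 of 26 fell, 2 rose; 16 and 2) and cytokines and chemokines (14 of 29 fell, 4 rose; 16 and 4) shifted down, and these 10 lists passed with either correlation. Cell cycle genes rose in 25 of 37 cases and fell in none (27 and 0 adjusted over the list alone), with Nusap1 at 1.54 and Aurkb at 1.04 (adjusted p = 0.0929 with an estimated correlation). MHC class II presentation (8 of 23 fell, 1 rose), cDC2 transcription factors (4 of 9 fell, 1 rose), ETS family and PU.1 partners (3 of 13 fell), interferon-stimulated genes (6 of 40 fell, 1 rose), AP-1 and BATF family (4 of 15 fell, 1 rose), immediate early and stress genes (8 of 21 fell) and neutrophil markers (2 of 28 fell), with the same counts adjusted over the list alone except for MHC class II presentation (9 fell, 2 rose), passed only with the preset correlation, with adjusted p = 0.0545, 0.0661, 0.0661, 0.615, 0.529, 0.263 and 0.615 with an estimated correlation.

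With the level of IRF4, 2420 genes were called, 896 higher and 1524 lower. The count was 1298 without IRF4-low replicate 2 and 1359 with only the groups compared. The Irf8 probeset also rose by 0.60 ± 0.12 (adjusted p = 0.00656), a call lost with only the groups compared (adjusted p = 0.0651) and without IRF4-low replicate 1 (0.0584) or IRF4-high replicate 1 (0.0553).

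The changes with the 2 levels were then set against each other, to see which were common and which differed between the factors. Batf3, Clec4b2 and Zfp366 rose with both. Zeb2, Csf1r, Tlr7, Nr1h3 and Ccr7 fell with both. Across all genes, 353 were higher at the high level of both factors, where independent lists would share 30.4 (odds ratio 37.6, 95% interval 31.5 to 45, Fisher's exact test), and 625 were lower with both, where 71.3 would be shared (odds ratio 40.9, 35 to 47.7). Opposite calls were fewer than for independent lists: 14 genes rose with IRF8 and fell with IRF4 (51.7 expected, Fisher's exact p = 2.08e-10), and 7 fell with IRF8 and rose with IRF4 (41.9 expected, exact p = 1.32e-11). Over all 19938 genes the changes correlated with a Pearson's r of 0.656 and a Spearman's rho of 0.504 (across genes, which are not independent replicates). The 978 shared calls became 521 without IRF8-low replicate 2 and 547 without IRF8-high replicate 1. For 49 of the 978 the interaction test also called a difference in size between the factors.

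**Figure D2:**
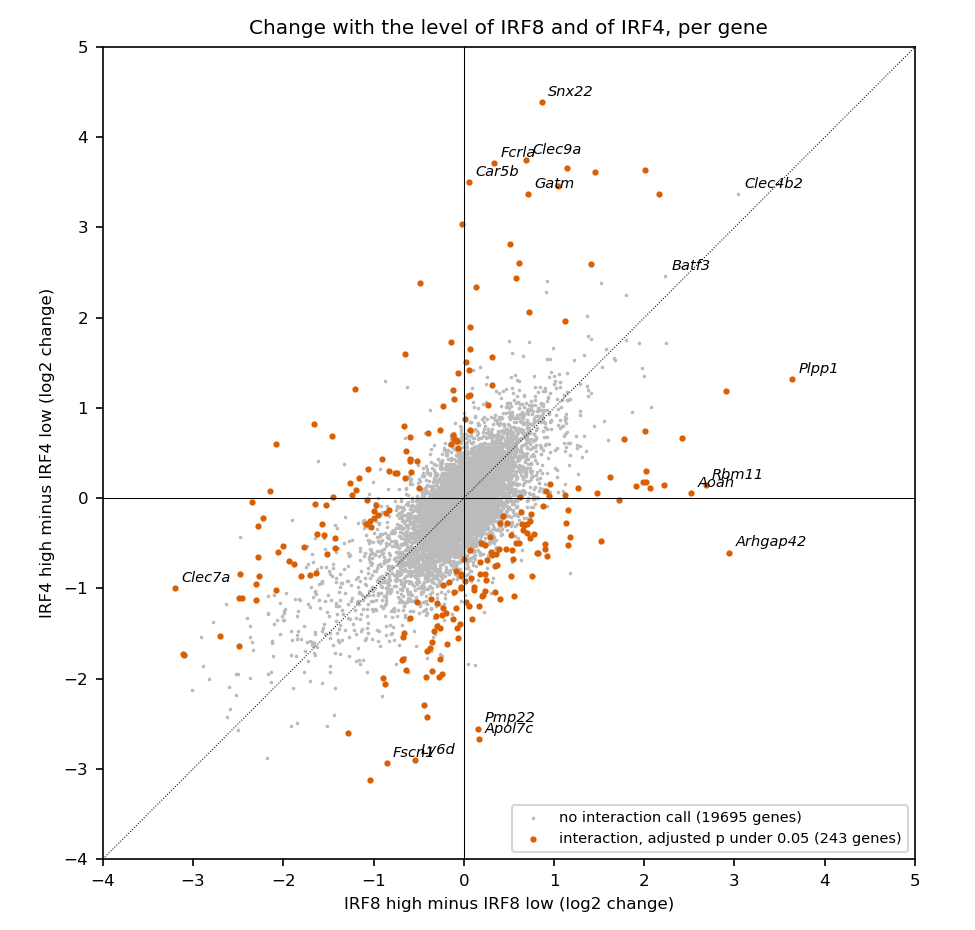
Log2 change with the level of IRF8 (horizontal axis) against that with IRF4 (vertical axis), 1 point per gene, with the 243 genes called in the interaction in orange. The changes have a Pearson's r of 0.656 and a Spearman's rho of 0.504 across genes, and Snx22, Clec9a and Fcrla stand far above the diagonal.

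The interaction, the level effect of IRF8 minus that of IRF4, called 243 genes, 133 with a more positive and 110 with a more negative effect of the IRF8 level. For 50 of them (36 positive and 14 negative), Plpp1, Rbm11 and Spib included, a group mean below background leaves the direction open. The cDC1 markers went both ways: 4 of 27 were positive, 2 of them open for this reason, and 4 negative (7 and 6 adjusted over the list alone), with a median of 0.06 and a camera adjusted p = 0.989. Some genes higher in wild-type cDC1 than in cDC2 had a more negative value: the interaction was −3.53 ± 0.32 for Snx22 (adjusted p = 0.000319), −3.06 ± 0.34 for Clec9a (adjusted p = 0.00158) and −2.66 for Gatm. Their levels at the low dose differed between the factors: Clec9a averaged 10.49 in IRF8-low and 5.27 in IRF4-low, and Snx22 9.98 and 6.14. Arhgap42 (3.55 ± 0.27, adjusted p = 0.000112) and Aoah, which encodes an enzyme that inactivates endotoxin (2.46), rose with IRF8 and were not called with IRF4 (−0.61 and 0.06). Clec7a (−2.21), Cd209a (−2.48) and Ccr2, a chemokine receptor of monocytes (−2.15), had a more negative effect of IRF8, and Pmp22 (2.71) a more negative effect of IRF4. Of the 243 genes, 34 were called lower at both high levels and 15 higher at both, 68 fell and 36 rose with IRF4 alone, and 35 fell and 34 rose with IRF8 alone. Among maturation and migration genes 6 of 36 had a positive interaction (1 left open by background) and none a negative one (22 and 1 adjusted over the list alone). Among cDC2 markers 1 was positive (left open) and 8 of 34 negative (1 and 13 adjusted over the list alone). Both of these lists have an adjusted p = 0.0936 with an estimated correlation. C-type lectin and Fc receptors (1 positive, 6 negative; 2 and 9 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation) and pDC markers (5 positive, of which 3 left open, and 1 negative; 8 and 2; adjusted p = 0.305) passed only with the preset correlation, as 4 other lists did. The 8 lists called became 5 without IRF4-low replicate 2, and the 243 genes became 129 without IRF8-high replicate 2 and 94 with only the groups compared.

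IRF8-high was set against IRF4-high to find genes that differ between the factors returned, whose amounts may differ as well. Xcr1 was at least 29.1-fold higher with IRF8 (5.26 ± 0.15, adjusted p = 5.99e-09), with means of 10.68 and 5.42. The tetraspanin gene Cd81 and the nucleotide receptor gene P2ry14 were 10.6-fold higher (3.40 each), Rbm11 at least 4.22-fold, and Clec9a 4.46-fold. With IRF4, Klk1b11, a kallikrein gene, was at least 70.8-fold higher (−7.16 ± 0.24, adjusted p = 2.03e-08), Rnase2a, a ribonuclease gene of the eosinophil type, at least 18-fold (−6.16 ± 0.28) and Clec10a at least 17.9-fold (−4.75 ± 0.17), beside Irf4 itself (−6.63). Of the cDC1 markers, 18 of 27 were higher with IRF8 and 1 lower (19 and 1 adjusted over the list alone), Naaa (1.96) and Cadm1 (1.90) among them. Of the cDC2 markers, 20 of 34 were lower and 3 higher (24 and 5 adjusted over the list alone), Mgl2 (−3.48) and Cd209a (−2.21) among them. These are the 2 of 21 called lists that passed with either correlation. C-type lectin and Fc receptors (11 of 26 lower, 3 higher; 15 and 4 adjusted over the list alone), monocyte and macrophage markers (8 of 32 lower, 2 higher; 15 and 3) and pDC markers (6 of 20 lower, 1 higher; 8 and 2) each have an adjusted p = 0.0811 with an estimated correlation. In all, 1196 genes were called, 672 higher with IRF8 and 524 higher with IRF4. Of those of at least 2-fold, 164 and 190 were. The count was 681 without IRF8-high replicate 2 and 627 with only the groups compared, and 13 lists were called without IRF8-high replicate 1.

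At the low level the same contrast again placed cDC1 genes on the IRF8 side and Klk1b11, Rnase2a and Clec10a on the IRF4 side. Clec9a was at least 25.4-fold higher in IRF8-low than in IRF4-low (5.22 ± 0.24, adjusted p = 3.07e-07), Ctla2b at least 20.5-fold, Snx22 14.3-fold, Xcr1 at least 7.32-fold and Itgae 9.61-fold. Klk1b11 (−5.52 ± 0.24, adjusted p = 1.77e-07), Rnase2a (−4.80), Clec10a (−3.80), Mgl2 (−3.53) and Ppbp (−3.20) were higher with IRF4. Of the cDC1 markers, 16 of 27 were higher with IRF8 and 1 lower (18 and 2 adjusted over the list alone). Maturation and migration genes were lower with IRF8 in 23 of 36 cases and higher in 1 (28 and 2 adjusted over the list alone), with Fscn1 at −2.67 and Ccr7 at −1.97. pDC markers were lower in 10 of 20 cases and higher in 1 (the same counts adjusted over the list alone), with Siglech, a pDC surface lectin, at −2.45 and Spib at −2.07. These 3 lists passed with either correlation. For cDC2 markers (9 of 34 lower, 4 higher; 11 and 7 adjusted over the list alone) the adjusted p = 0.44 with an estimated correlation. In all, 936 genes were called, 405 higher with IRF8 and 531 higher with IRF4. The count was 584 without IRF4-low replicate 2 and 500 with only the groups compared.

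Calls between the factors overlapped across the levels. At both levels 222 genes were higher with IRF8 (13.7 expected for independent lists, odds ratio 51.4, Fisher's exact p = 3.91e-227) and 199 higher with IRF4 (14 expected, odds ratio 35.2, exact p = 5.34e-185). In opposite directions, 10 genes (17.9 expected, Fisher's exact p = 0.0512) and 4 genes (10.6 expected, exact p = 0.039) were called.

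The genes that separate the wild-type subsets were followed through the transduced cells, to ask whether they move with the level or with the factor. These lists were chosen by the wild-type comparison of this study, with its variance pooled over all arrays. Their counts are therefore not evidence from outside the study. Of 280 genes higher in wild-type cDC1, 115 rose and 9 fell with the IRF8 level (150 and 16 adjusted over the list alone; median 0.39), and 128 rose and 11 fell with the IRF4 level (158 and 14; median 0.46). Of 579 genes higher in wild-type cDC2, 258 fell and 11 rose with the IRF8 level (331 and 19 adjusted over the list alone; median −0.46), and 391 fell and 6 rose with the IRF4 level (453 and 9; median −0.74). Between the factors, cDC1 genes were higher with IRF8 in 130 cases and lower in 15 at the high level (median 0.45), and higher in 123 and lower in 5 at the low level (median 0.50). cDC2 genes were lower with IRF8 in 126 cases and higher in 38 at the high level (median −0.15), and lower in 192 and higher in 16 at the low level (median −0.38). All 8 shifts passed camera with either correlation; the weakest had an adjusted p = 0.00223 with an estimated correlation. In the interaction, cDC2 genes had a positive median of 0.25 (52 positive, 25 negative; adjusted p = 0.00651 with an estimated correlation). Over the 461 of them above background in all 4 transduced groups it was 0.207 and passed camera only with the preset correlation (adjusted p = 0.00186, and 0.116 with an estimated correlation). The cDC1 genes had a median of −0.04 (15 positive, 26 negative; adjusted p = 0.228 with an estimated correlation). That median was −0.013 without IRF4-low replicate 2 and −0.016 without IRF8-high replicate 1, and −0.089 without IRF8-low replicate 2 or IRF8-high replicate 2.

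**Figure D3:**
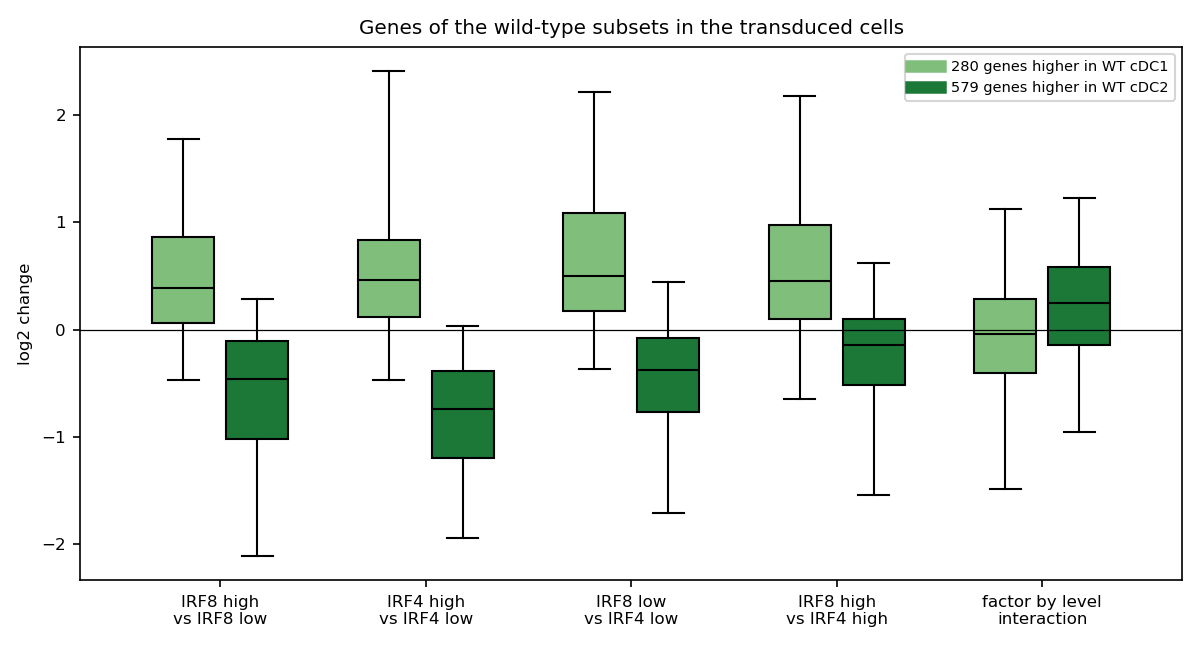
Log2 changes in the transduced cells (vertical axis) of the 280 genes higher in wild-type cDC1 and the 579 higher in wild-type cDC2, for each comparison on the horizontal axis. Boxes span the quartiles with a line at the median and whiskers run from the 5th to the 95th percentile; the medians are 0.39 and −0.46 for the IRF8 level and 0.46 and −0.74 for the IRF4 level.

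Each high level was set against wild-type cDC1. The transduced cells differ from wild-type cells in genotype, in the vector and in the sort gate, which has no CD24 or CD172 step, so these differences cannot be told apart. No batches are given, so a batch that differs between transduced and wild-type arrays cannot be told apart from them either. In IRF8-high, the level of Irf8 differed from wild-type cDC1 by 0.10 ± 0.12 (adjusted p = 0.632), and cDC1 markers were not called as a group (5 of 27 higher, 9 lower; 6 and 10 adjusted over the list alone). Id3, an inhibitor of DNA binding, was at least 69.7-fold higher (6.49 ± 0.14, adjusted p = 1.87e-10), the progenitor marker Cd34 44.5-fold, the complement gene C1qb at least 29.1-fold, the chemokine gene Pf4 26.7-fold and Sirpa 18-fold. The receptor kinase gene Kit (−5.16 ± 0.22), the tight-junction gene Cldn1 (−4.04), the interleukin-12 receptor gene Il12rb2 (−3.96) and the inhibitory Fc receptor gene Fcgr2b (−3.73) were lower. The probeset named Kcnma1 (8.43 ± 0.15) and Thy1, a surface glycoprotein (5.54 ± 0.11), stood far above wild type in every transduced group. Kcnma1 is uncertain, since a second probeset of the gene differed by −0.042 between all transduced and all wild-type arrays and lay at background in all of them. Of 32 monocyte and macrophage markers 21 were higher and 3 lower (22 and 3 adjusted over the list alone; adjusted p = 0.0677 with an estimated correlation). Interferon-stimulated genes (17 of 40 higher, 2 lower; 19 and 2 adjusted over the list alone), cDC2 markers (16 of 34 higher, 4 lower; 19 and 5) and cell cycle genes (16 of 37 higher, 0 lower; 21 and 0) have adjusted p = 0.672, 0.298 and 0.575 with an estimated correlation. None of the 10 called lists passed with it. In all, 4347 genes were called, 2321 higher and 2026 lower, and 2755 without cDC1 replicate 1.

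In IRF4-high, 20 of 27 cDC1 markers were lower than in wild-type cDC1 and 3 higher (the same counts adjusted over the list alone), Xcr1 at least 30.9-fold (−5.34 ± 0.15, adjusted p = 1.99e-09) and Cadm1 by −1.75. Of 34 cDC2 markers 24 were higher and 4 lower (25 and 4 adjusted over the list alone), with Clec10a at 5.49 ± 0.17 and Sirpa at 4.69. C-type lectin and Fc receptors (20 of 26 higher, 4 lower; the same counts adjusted over the list alone), with Clec4n at 4.78, and monocyte and macrophage markers (22 of 32 higher, 2 lower; 23 and 2), with C1qb at 5.67 and C1qc at 4.78, were higher as groups. These 4 lists passed with either correlation. Interferon-stimulated genes were higher in 24 of 40 cases and lower in 4 (25 and 4 adjusted over the list alone; adjusted p = 0.394 with an estimated correlation), with Rtp4 at 5.87 and Ifit3 at 4.28. Klk1b11 (7.44), Rnase2a (6.27), Id3 (6.17) and Pf4 (6.10) were among the largest rises, beside Irf4 (5.37). The Irf8 probeset, in cells without a functional Irf8 gene, was lower by 2.07 on the log2 scale (−2.07 ± 0.12). In all, 4965 genes were called, 2491 higher and 2474 lower, and 3298 without cDC1 replicate 1.

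Each low level was set against wild-type cDC2, under the same limits. The low levels did not match the signals of both factors in wild-type cDC2. Irf8 read 12.45 and 12.46 in the IRF8-low arrays, against 10.39 and 10.44 in wild-type cDC2, and Irf4 stood at −4.64. In IRF8-low, maturation and migration genes were lower in 34 of 36 cases and higher in 1 (the same counts adjusted over the list alone): Fscn1 was 46-fold lower (−5.52 ± 0.22, adjusted p = 1.59e-08), Il12b, a subunit of interleukin-12, stood at −5.04, Ccr7 at −3.82 and Relb at −2.54. cDC1 markers were higher in 19 of 27 cases and lower in 3 (19 and 4 adjusted over the list alone), with Clec9a at 6.01 ± 0.24. Toll-like receptors (10 of 15 higher, none lower; 10 and 1 adjusted over the list alone), with Tlr3 at 4.25, and monocyte and macrophage markers (20 of 32 higher, 3 lower; 22 and 3) were higher. These 4 lists passed with either correlation. Interferon-stimulated genes (23 of 40 higher, 3 lower; 24 and 5 adjusted over the list alone) and sterol synthesis (8 of 17 lower, 2 higher; 9 and 2), with Idi1 at −1.62, have adjusted p = 0.53 and 0.52 with an estimated correlation. Pf4 (6.56), Id3 (6.22) and Cd34 (5.58) were among the largest rises. In all, 4953 genes were called, 2661 higher and 2292 lower.

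In IRF4-low, 33 of 36 maturation and migration genes were lower than in wild-type cDC2 and 1 higher (the same counts adjusted over the list alone), with Il12b at −4.10 ± 0.19 (adjusted p = 1.18e-07), Ccl22 at −2.91 and Fscn1 at −2.85. Monocyte and macrophage markers were higher in 19 of 32 cases and lower in none (20 and 0 adjusted over the list alone), with C1qb 62.4-fold higher (5.96 ± 0.20). Both lists passed with either correlation. cDC1 markers were not called as a group (7 of 27 higher, 5 lower; 10 and 8 adjusted over the list alone). Interferon-stimulated genes (25 of 40 higher, 2 lower; 27 and 2 adjusted over the list alone), sterol synthesis (10 of 17 lower, none higher; 12 and 0) and lysosome and lipid handling (12 of 23 higher, 2 lower; 12 and 2) have adjusted p = 0.458, 0.427 and 0.208 with an estimated correlation. Pf4 was at least 104-fold higher (7.60 ± 0.23), Rnase2a at least 9.14-fold and the amino acid transporter gene Slc7a8 at least 29.3-fold. The Irf8 probeset differed by −0.16 ± 0.12 (limma adjusted p = 0.412), although these cells lack a functional Irf8 gene. Irf4 read 11.28 and 10.93 in the IRF4-low arrays, above the 9.20 and 9.24 of wild-type cDC2. In all, 4618 genes were called, 2602 higher and 2016 lower, and 2846 without cDC2 replicate 1.

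**Figure D4:**
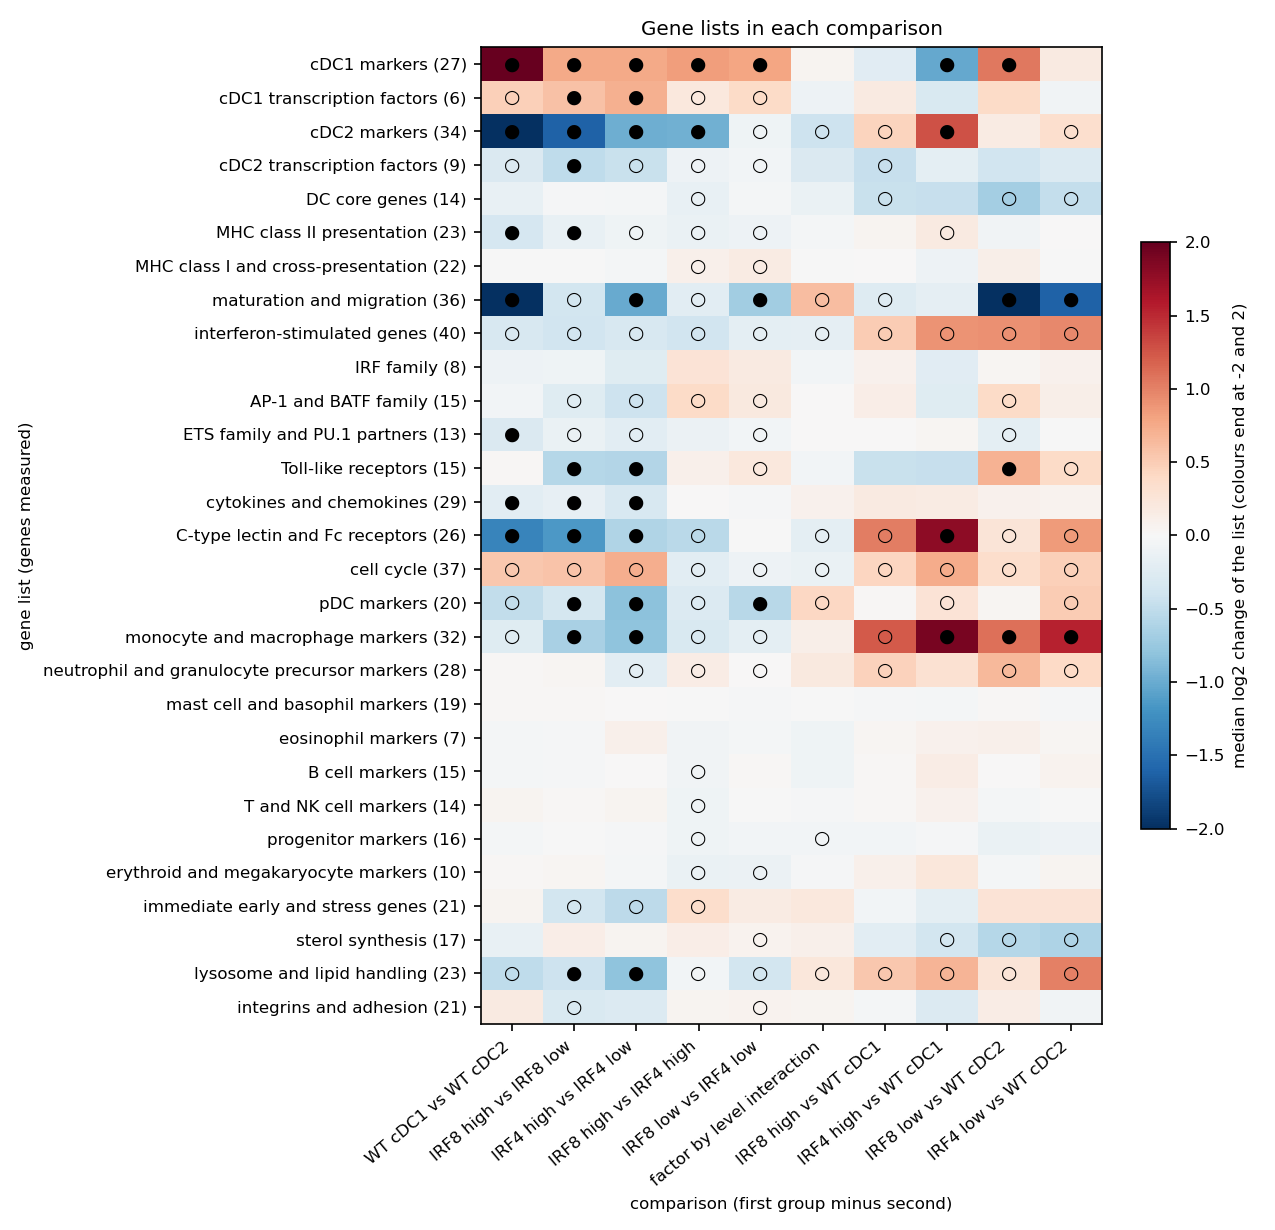
Median log2 change of each gene list (vertical axis) in each comparison (horizontal axis), with colours ending at −2 and 2. Filled dots mark lists that passed camera with either correlation and open circles those that passed only with the preset one; monocyte and macrophage markers fall at both high levels (medians −0.65 and −0.80) and have positive medians in all 4 comparisons with wild-type cells.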

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

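Every result here was picked out by the interaction test, which was fixed before the data were examined; the check against background was chosen after the results were seen. A value is the log2 change with the level of IRF8 minus that with the level of IRF4. A negative value can be a fall with IRF8 or a rise that is smaller than with IRF4. Clec9a, for example, went from 10.49 to 11.17 with IRF8 and from 5.27 to 9.02 with IRF4. The interaction was called for 243 genes, of which those that the naming rule selects follow, with no explanation tested. Of 27 cDC1 markers, 4 were called positive and 4 negative (7 and 6 adjusted over the list alone; median 0.06): Plpp1 (2.32) and Cd36 (1.07) among the former, and Snx22 (−3.53), Clec9a (−3.06), Tlr3 (−2.41) and Itgae (−1.997) the latter. The enzyme gene Gatm (−2.66) was negative. So were the receptor and lectin genes Fcrla (−3.38), Cd209a (−2.48), Cd209d (−2.31), Clec7a (−2.21), Ccr2 (−2.15), Kit (−1.63), Cd300c (−1.39), Itgax (−1.13) and Itga5 (−0.81), and the surface protein genes Cldn1 (−2.68), Ms4a4c (−2.23), Cd34 (−2.21), Cd3g (−1.83) and Spn (−1.28). Car5b (−3.45), Xlr (−3.06), Dnah6 (−2.87), Rtl8c (−2.51) and H2-Oa (−0.89) completed the negative side. A group mean below background leaves the direction open for Adam23, Car5b, Cd3g, Dnah6, Fcrla, Plpp1, Ppbp, Ranbp17, Rbm11 and Spib, whose values describe the signals as measured; it limits the size, not the direction, for Arhgap42, Cldn1, Clec9a and Xlr.

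Positive values were found for Arhgap42 (3.55), Rbm11 (2.54), Aoah (2.46) and Ranbp17 (2.08), all of which rose with IRF8. The maturation and migration genes Fscn1 (2.09), Apol7c (2.84), Adam23 (1.36) and Stat4 (1.10) were positive too, as were Etv3 (0.87), Pmp22 (2.71), Ly6d (2.36), Ppbp (2.08), Spib (1.85), H2-Eb2 (1.28), Blnk (1.19), Fabp5 (0.96) and Ifi30 (0.76). The 579 genes higher in wild-type cDC2 had a median of 0.25. It was 0.207 over the 461 of them above background in all 4 transduced groups, and passed camera there only with the preset correlation (adjusted p = 0.00186, and 0.116 with an estimated correlation). The calls of Fabp5, Cd36, Blnk, Ppbp, Ifi30, Ly6d, Itga5, Etv3, Cd209d, Ms4a4c, Kit, Tlr3, Xlr, H2-Oa, H2-Eb2, Dnah6 and Fscn1 were lost under at least 1 alternative.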

How the results depend on the processing

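The replicate block fitted by set, the crossed numbers and the limit to genes above background in the 4 transduced groups were chosen after seeing the data; all other alternatives were fixed before. Among the called results for named genes, 0 changed direction under the alternatives run. Directions of other genes were not checked. The intensity trend, array weights, only the groups compared, the replicate block over all arrays and the stricter thresholds leave the changes as they were. These settings could not reverse a direction. For the 899 called results for named genes, the alternatives other than thresholds and left-out arrays gave 9880 values. Of these, 9669 stayed on their side of the threshold and 211 were no longer called. Under at least 1 such alternative, 116 of the 899 results lost their call. Some calls were also lost with 1 array left out. Most arrays lie outside the groups of a given pairwise comparison, and leaving them out cannot alter its changes. Counts of calls moved by more than 1.5 times under these settings, and the cause was not tested unless named. With an estimated correlation in camera, which allows for genes of a list moving together, the called lists went from 14 to 7 (wild-type subsets), 18 to 11 (IRF8 level), 18 to 10 (IRF4 level), 21 to 2 (factors at the high level), 19 to 3 (factors at the low level), 8 to 0 (interaction), 10 to 0 (IRF8-high against cDC1), 10 to 4 (IRF4-high against cDC1), 13 to 4 (IRF8-low against cDC2) and 12 to 2 (IRF4-low against cDC2). With only the groups compared, 873 genes were called for the IRF8 level, 1359 for the IRF4 level, 627 and 500 between the factors at the high and low level, and 94 in the interaction. The other counts moved less, in either direction (3880 for the wild-type subsets, 4590 and 4453 for IRF8-high and IRF4-high against cDC1, and 4893 and 4936 for IRF8-low and IRF4-low against cDC2). At an adjusted p under 0.01, which is stricter by construction, the counts were 2040 (wild-type subsets), 791 (IRF8 level), 1260 (IRF4 level), 641 and 513 (factors, high and low), 94 (interaction), 2739 and 3137 (IRF8-high and IRF4-high against cDC1) and 2905 (IRF4-low against cDC2). Calls of at least 2-fold numbered 859, 410, 518, 354 and 299 for the first 5 of these, 768 and 962 against cDC1, and 1089 and 837 for IRF8-low and IRF4-low against cDC2. Among them the share lower was 67.4% for the wild-type subsets and 73.2% for the IRF8 level, against 50.3% and 58% of all calls. Between the factors at the high level the balance turned, from 43.8% lower of all calls to 53.7% lower of those of at least 2-fold. No normalization alternative moved that share by over 10 percentage points or the median of all genes by over 0.1.

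With 1 array left out, the lone sample of its group was assumed to vary like the other groups. Calls then ranged from 1947 to 3319 (wild-type subsets), 812 to 1825 (IRF8 level), 1298 to 2513 (IRF4 level), 681 to 1231 and 584 to 1059 (factors, high and low), 129 to 230 (interaction), 2755 to 4609 (IRF8-high against cDC1), 3298 to 4989 (IRF4-high against cDC1) and 2846 to 4852 (IRF4-low against cDC2). The lists called ranged from 13 to 21 (factors at the high level) and 5 to 10 (interaction), the overlap of IRF8 and IRF4 level calls from 521 to 983, and the median interaction of genes higher in wild-type cDC1 from −0.089 to −0.013. That median was nearest to 0 without IRF4-low replicate 2 (−0.013) and farthest without IRF8-low replicate 2 or IRF8-high replicate 2 (−0.089). The lowest counts came without IRF4-low replicate 2 (1298, 584 and 5), IRF8-low replicate 2 (812 and 521), IRF8-high replicate 1 (13), IRF8-high replicate 2 (681 and 129), cDC1 replicate 1 (2755 and 3298) and cDC2 replicate 1 (1947 and 2846).

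The titles number the replicates 1 and 2, but nothing says that a number marks a shared culture, and each comparison has only 2 pairs. Replicate differences correlated at 0.18 to 0.296 among the 4 transduced groups and at 0.261 between the wild-type groups, but at −0.105 to 0.0547 between these sets. With the replicate number as a block over all arrays, 3486, 1960, 2876, 1406, 1126 and 345 genes were called in the first 6 contrasts, and 4761, 5357, 5370 and 5024 against wild-type cells; no called result for a named gene was lost. Blocks fitted by set called 428 genes in the interaction and gave an overlap of IRF8 and IRF4 level calls of 1481. With crossed numbers in wild-type cDC2 the IRF4-low comparison called 4941 genes. The arrays carry no detection calls; 11485 of the 19938 genes lay above the overall median of 6.14 in at least 2 arrays, and dimmer genes were measured close to the floor. Over the 11366 genes above background in the 4 transduced groups, the interaction called 170 genes. There the medians of genes higher in wild-type cDC1 and in cDC2 were −0.0492 and 0.207, and both passed camera with the preset correlation only (adjusted p = 0.00186 each, and 0.193 and 0.116 with an estimated correlation).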

Other observations

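All tests of explanations in this part were chosen after the values were seen. Batf3 stood above wild-type cDC1 at the high level of either factor, by 2.57 ± 0.14 on the log2 scale with IRF8 (5.94-fold, limma adjusted p = 3.75e-07) and 2.64 ± 0.14 with IRF4 (6.24-fold, adjusted p = 2.13e-07), with both arrays above both wild-type arrays each time. Spi1, which encodes PU.1, a partner of both factors, was 3.12-fold and 3.24-fold higher than in wild-type cDC1. Il18 was 4.29-fold and 4.35-fold higher. Bcl6 was lower at −1.16 and −1.44, and Notch2 at −0.95 and −1.20. The cDC1-associated gene Rab43 was lower at −1.07 and −1.67.

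Granulocyte genes also stood above wild type. Of 28 neutrophil and granulocyte precursor markers, 13 were higher and 2 lower in IRF8-high than in wild-type cDC1 (17 and 2 adjusted over the list alone), 16 were higher and none lower in IRF8-low than in wild-type cDC2 (the same over the list alone), and 12 were higher and 1 lower in IRF4-low than in wild-type cDC2 (14 and 1); these passed camera only with the preset correlation (adjusted p = 0.575, 0.397 and 0.453 with an estimated correlation). In IRF4-high, 7 were higher and 1 lower than in wild-type cDC1 (the same adjusted over the list alone), and the list was not called. Mpo, the myeloperoxidase gene, was at least 6.54-fold higher in IRF8-low, at least 4.43-fold in IRF4-low and 5.35-fold in IRF4-high, and Mmp8 was at least 4.61-fold higher in IRF8-low. Irf7, an interferon-induced member of the IRF family, was 9.47-fold higher in IRF8-low and 7.07-fold in IRF4-low than in wild-type cDC2.

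The probeset named Kcnma1 lay between 12.87 and 13.38 in the 8 transduced arrays and between 4.31 and 4.74 in the 4 wild-type arrays (at least 167-fold), and Thy1 between 11.90 and 12.71 against 6.97 to 7.20 (36.6-fold). The second Kcnma1 probeset, which lists the gene's RefSeq transcripts, differed by −0.042 (95% interval −0.164 to 0.08). It lay at background in every array, so nothing shows that it can detect the transcript, and transcription of the Kcnma1 gene stays open. A sequence carried by the vector would be expected to rise with the level of the transgene. The Thy1 change was 0.307 with IRF4 (95% interval 0.081 to 0.534) and 0.347 with IRF8 (0.121 to 0.573). The limma adjusted p was 0.0897 and 0.0802 over all probesets. A vector marker could give such rises, but they do not exclude the cells' own Thy1. For the Kcnma1 probeset the changes were −0.119 and −0.217 (95% interval of the latter −0.562 to 0.129), so whether it may read vector sequence stays open, as the vector's sequence was not used here.

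Monocyte and macrophage markers were called higher than in wild type, and lower at the high level of either factor, in the comparisons made. The former call was lost for IRF8-high against cDC1 (adjusted p = 0.0677 with an estimated correlation). The sort gate (MHC class II+ CD11c+ B220−) names no marker that would remove macrophages. Fewer cells of 1 macrophage kind at the high level could lower all of their markers alike, so the markers at least 4-fold above both wild-type groups at the low level were compared. Genes that differ at least 2-fold between the wild-type subsets, such as Cd14, can also change with the subset and were left out. The SD of the changes was then 1.45 times their median SE over 6 markers with IRF8 (95% interval 0.903 to 3.55) and 2.01 times over 9 markers with IRF4 (1.36 to 3.85), so both intervals hold the bound of 2 that was set. With the subset genes left in, the values were 3.03 over 9 markers (2.05 to 5.81) and 3.05 over 13 (2.19 to 5.04), above the bound, so the outcome turns on those genes. A lower share of 1 macrophage kind is therefore not excluded for either factor, and a change within the cells, or several kinds changing at once, stays open too.

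Genes that separate all transduced from all wild-type arrays by at least 2-fold numbered 405, 275 higher and 130 lower in the transduced cells. Sequence of another strain carried along with the targeted loci might place such genes near Irf4 and Irf8. Of 186 tested neighbours, 6 were among them (3.23% against 2.02% of other genes; odds ratio 1.62, 95% interval 0.582 to 3.62, Fisher's exact p = 0.284), too few to tell. The genotype, the vector and the sort gate differ between these cells as well, and no test here separates them. A batch that differs between transduced and wild-type arrays is not excluded either, as no batches are given.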
